A study of Danio rerio with 4 samples.

How the data were processed

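Total RNA of whole zebrafish embryos at the 6-somite stage was sequenced in 4 libraries. 2 libraries came from wild-type embryos of the AB strain and 2 from embryos homozygous for the bns297 allele of npas4l. Per the labels' protocols, RNA was isolated with a miRNeasy micro kit and treated with DNase on the column. Libraries were made from 10 ng of total RNA with the SMARTer Stranded Total RNA kit for pico inputs and sequenced as single reads of 75 bases on a NextSeq500. Such libraries are primed randomly and keep RNAs without a poly(A) tail, such as histone mRNAs and small nuclear RNAs, so these RNAs were measured as well. The labels do not say how many embryos or clutches stood behind each library. The p-values below therefore rest only on spread between these libraries, which may be partly technical, and mostly on spread pooled over genes of similar value.

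Per the submitters' processing notes, the tools were FastQC, STAR 2.4.0a, featureCounts 1.4.5-p1 from Subread and DESeq2, and the builds named were danRer10 and GRCz10. The notes give the tools without settings, so the strand setting of the counting is not given in the sources used here. The deposited table held 24235 Ensembl genes with their symbols, biotypes and coordinates, and 1 value per gene and library. The deposited values are a score: whole numbers that are gene counts scaled by 1 factor per library and rounded, not raw counts. This was read from the values themselves. At regular intervals wild-type replicate 1 and mutant replicate 2 skipped a whole number, while wild-type replicate 2 and mutant replicate 1 held a number about as often as its neighbours together. From these intervals, 1 read was worth 1.09 and 0.898 in wild-type replicates 1 and 2, and 0.983 and 1.01 in mutant replicates 1 and 2. The rounding merges or splits values, so the counts could not be recovered exactly. Every gene in the table reached a value of at least 4 in some library. Throughout, a normalised value is this deposited number.

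The test planned for raw counts could not be used on this unit, and the test fixed for normalised values before the data were examined took its place. Values were transformed as log2(value + 1), genes with a mean value of at least 10 over the 4 libraries were kept (16653 genes), and mutants were compared with wild type by limma-trend (limma 3.58.1 in R 4.3.3) with group as the only term. p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed the test at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. limma-trend drew each gene's variance toward the trend over genes of similar value, with 83.6 prior degrees of freedom. With 2 libraries per group, each standard error and p-value therefore reflected mostly that trend and not the gene's own spread. The median standard error of a log2 fold change was 0.27 over all genes tested and 0.20 over genes with a mean value of at least 50. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with Matplotlib 3.10.9.

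18 gene lists were fixed before the data were examined. They cover haemangioblast regulators, endothelium, primitive erythroid and myeloid cells, cardiac mesoderm and 13 other tissues, stages or responses. List members were matched by the symbol in the table or by the current symbol of the same gene ID. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 18 lists. Alternatives were camera with a correlation estimated for each list, and fry. With an estimated correlation camera rests on the few residual degrees of freedom of the 4 libraries. A list can therefore fail there even where its members are not correlated. Members past the test were counted over all genes tested and adjusted over the list alone. Shares of the summed values taken by 5 gene families, and by nuclear ribosomal RNA, added after seeing the data, were computed for each library.

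The genes named were fixed by rule before the data were examined. The rule took npas4l, etv2, tal1 and lmo2. In each direction it took up to 10 genes with the largest log2 fold change among those past the test with a mean value of at least 50 and both mutant libraries beyond both wild-type libraries. It also took up to 4 members with the smallest p-values from each of the haemangioblast, endothelium, erythroid, myeloid and cardiac lists, and up to 2 from any other list that passed its test or held a called member. Other genes are named where the text says that they were chosen after their values were seen. The mutated gene npas4l itself was not analysed here, so its own RNA gave no check of the labels. Coordinates are those of the deposited table.

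The code was tested on simulated data. There were 5 simulations of the mutant against wild-type comparison over 24235 genes. Values were drawn with 1 spread shared by all genes (negative binomial dispersion 0.0143), then scaled and rounded as above. That spread was estimated from the replicates of genes with a mean value of at least 50. Genes varied independently, and differences in spread between genes, or in low values between libraries, were not simulated. The shares below are therefore those of a simpler case than these data. In each simulation 200 genes were changed. Of the genes changed 1.5-fold, 8.06% were called in the right direction. The share was 50.7% at 2-fold and 87.6% at 4-fold. Over all 5 simulations 3 unchanged genes were called. A planted list of 15 genes lowered by 0.7 on the log2 scale passed camera in 5 of the 5 simulations, and in 4 with an estimated correlation. The only other list simulated was an unchanged list, so the adjustment there ran over fewer lists than in the data. These passes therefore do not show how often such a list would pass in these data, with either form of camera.

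Alternatives fixed beforehand changed the scaling, the filter on low values, the pseudocount, the variance model (limma-voom on the deposited values, and robust estimation), the threshold and the set of libraries, and added a replicate block. limma-voom also scaled each library to its total, so it did not change the variance model alone. Quantile normalization, and a form of leaving out a library that drops genes with tied values, were added after seeing the data.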

Results

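The transcriptome of whole zebrafish embryos was measured by RNA sequencing at the 6-somite stage, when the lateral plate mesoderm that will form vessels and blood is already set apart. Wild-type AB embryos (2 libraries) were compared with embryos homozygous for the bns297 allele of npas4l (2 libraries). npas4l encodes a bHLH-PAS transcription factor that is required for most endothelial and blood cells to form, and the comparison asked which RNAs depend on it at this stage.

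The normalised values summed to 7984958 and 8101165 in wild-type replicates 1 and 2, and to 8237748 and 7272902 in mutant replicates 1 and 2. The spacing of the values put the reads in genes at 7333000, 9022000, 8378000 and 7208000 in the same order, rounded. Mitochondrially encoded RNA took between 25.3% and 26.6% of each library. Mutant replicate 2 stood apart from the other 3 libraries. It listed 299 genes at 0, against 2444 to 3000 in the others, and 19481 genes at 10 or more, against 15954 to 16069. Across genes, which are not independent replicates, its Pearson correlation with the other libraries was 0.937 to 0.944, against 0.959 to 0.967 among those 3. The first principal component, with 50.3% of the variance, separated this library from the other 3, not the mutants from the wild type. Among genes with a mean value of 3 to 10 in the other libraries, its excess was larger in genes with a longer genomic span.

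**Figure D1:**
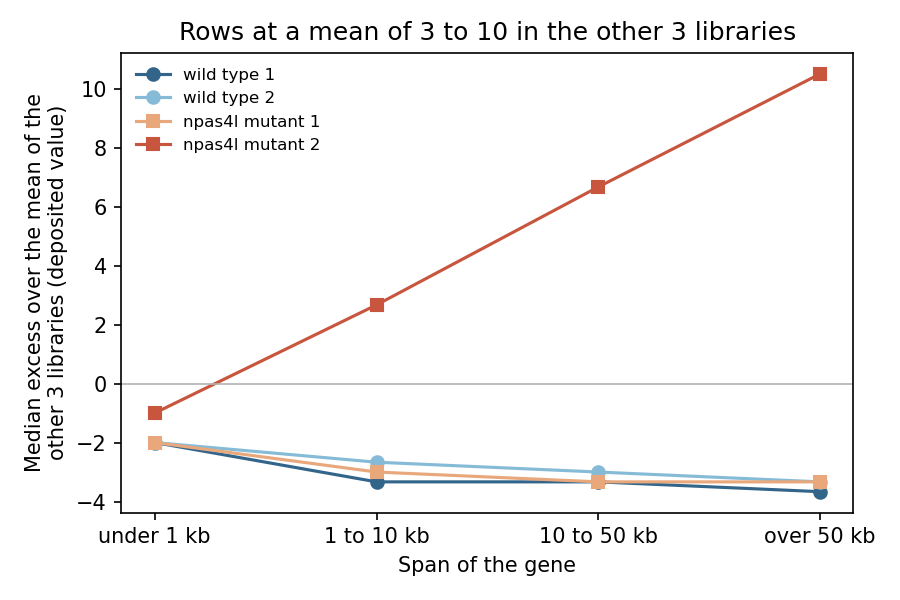
Median difference between each library's normalised value and the mean of the other 3 libraries (y axis), for genes with a mean of 3 to 10 in those 3, by genomic span of the gene (x axis); each point is 1 library. Mutant replicate 2 goes from -1 in genes under 1 kb to 10.5 in genes over 50 kb, and the other libraries lie between -3.67 and -2.

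In npas4l mutants, 4 regulators of the early endothelial and blood programme fell. tal1, a bHLH factor needed for blood stem and progenitor cells, fell from 164.5 ± 2.12 normalised reads in wild type to 10.5 ± 3.54 in mutants (mean ± SD, n = 2 in each group here and below). lmo2, which encodes a LIM-domain partner of Tal1, fell from 210.5 ± 0.707 to 47.0 ± 19.8. etv2, an ETS factor that starts endothelial differentiation, fell from 269 ± 35.4 to 106.5 ± 29.0, and gfi1aa, a transcriptional repressor expressed in early red blood cells, fell from 82.5 ± 13.4 to 11 ± 1.41. In the other direction 1 gene rose, the circadian clock gene per1b, from 188.5 ± 4.95 to 460.5 ± 17.7.

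On the log2 scale the change of tal1 (ENSDARG00000019930, chromosome 22, 16509305 to 16519060, plus strand, GRCz10) was -3.88 ± 0.40 (SE) with a limma adjusted p of 3.27e-11. The change of lmo2 (ENSDARG00000095019, chromosome 18, 38307869 to 38315657, plus strand) was -2.20 ± 0.26 with an adjusted p of 8.49e-09. For etv2 (ENSDARG00000053868, chromosome 16, 42058781 to 42063826, minus strand) it was -1.35 ± 0.21 with an adjusted p of 2.50e-05. For gfi1aa (ENSDARG00000020746, chromosome 2, 10983145 to 11002050, plus strand) it was -2.79 ± 0.49 with an adjusted p of 4.07e-04. per1b (ENSDARG00000012499, chromosome 7, 50547395 to 50571221, plus strand) changed by 1.28 ± 0.17 with an adjusted p of 3.62e-07. In each of these 5 genes both mutant libraries lay beyond both wild-type libraries, and no other gene of the table overlapped them. The adjusted p-values depended on the variance model, which limma-voom changed together with the scaling of the libraries. tal1, lmo2, etv2 and per1b kept their calls with limma-voom, but at adjusted p-values of 0.0421, 7.37e-04, 0.00407 and 2.49e-05. With limma-voom the call of gfi1aa was lost, at an adjusted p of 0.516 (range over all alternatives 3.76e-05 to 1).

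3 other genes fell. morc3b (ENSDARG00000043271, chromosome 1, 46487297 to 46510931, plus strand), a member of the MORC family of chromatin-binding ATPases, fell from 93.5 ± 13.4 to 24.5 ± 6.36 normalised reads, a log2 change of -1.91 ± 0.37 (SE) with an adjusted p of 0.00447. Its call was lost with limma-voom, at an adjusted p of 0.327 (range over all alternatives 0.00129 to 1). The remaining 2 were histone H2B genes in 1 cluster on chromosome 7. FP236812.4 (ENSDARG00000086751, 73627742 to 73628116, minus strand) changed by -1.43 ± 0.20 with an adjusted p of 1.62e-06. FP236812.8 (ENSDARG00000104554, 73590418 to 73590792, minus strand) changed by -0.94 ± 0.19 with an adjusted p of 0.0135. Histone genes are near-identical copies whose reads the counting can split, so both values are uncertain. The change of FP236812.8 also rested largely on mutant replicate 2, and that of FP236812.4 in part. FP236812.4 stood at 103 and FP236812.8 at 142 there, against 244 and 334 in mutant replicate 1. The wild-type libraries held 411 to 445. The standard errors, drawn toward the trend over genes of similar value, do not show this difference between the mutant libraries. Without mutant replicate 2 the log2 fold changes of FP236812.4 and FP236812.8 were -0.81 and -0.32. The call of FP236812.8 was lost with a pseudocount of 10, with limma-voom and with quantile normalization (adjusted p 0.0681, 0.131 and 0.679; range over all alternatives 4.01e-05 to 1).

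**Figure D2:**
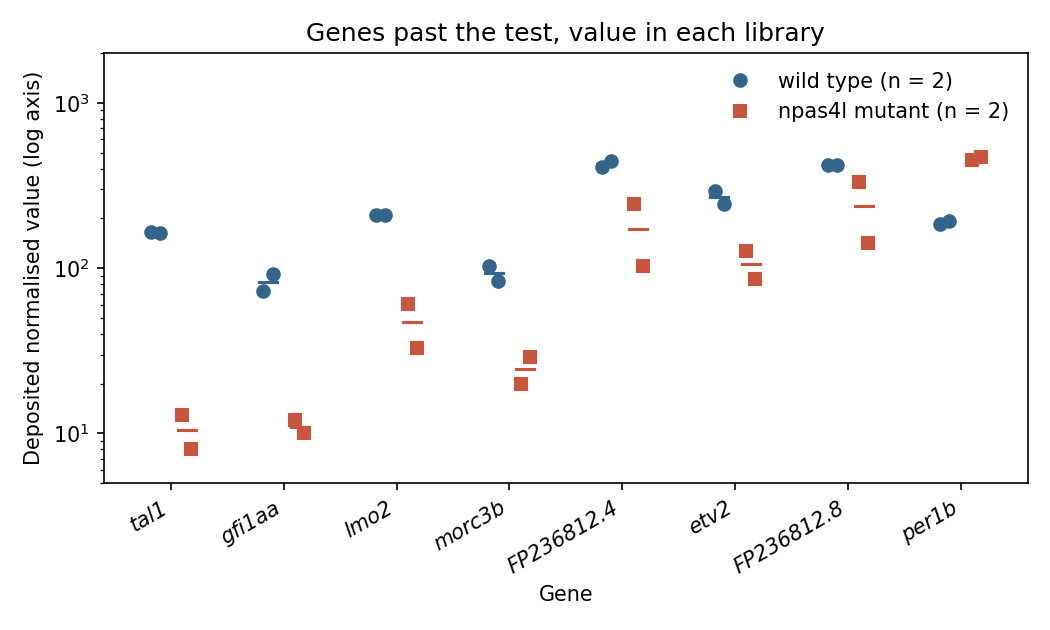
Normalised value of the 8 genes past the test (log y axis) in each library, with genes on the x axis in order of log2 fold change; circles are the 2 wild-type libraries, squares the 2 npas4l mutant libraries, and short lines the group means, which the symbols hide where both libraries are close. tal1 stands at 166 and 163 in wild type and at 13 and 8 in mutants, and per1b at 185 and 192 against 448 and 473.

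Over all 16653 genes tested, 8 passed at an adjusted p under 0.05, 1 higher and 7 lower in mutants. At an unadjusted p under 0.05 there were 624 genes, 306 higher and 318 lower, where chance alone would give 833. The groups of 29.4% of the genes did not overlap, against 33.3% by chance. Leaving out any 1 library in the planned fit called 0 genes, because tied values in the remaining pair gave variances of 0; at an unadjusted p under 0.05 these fits held 218 to 1586 genes. With tied genes left out, chosen after seeing the data, the count was 7 without wild-type replicate 1, 6 without wild-type replicate 2, 219 without mutant replicate 1 and 21 without mutant replicate 2. Of the 8 genes, 4, 5, 7 and 7 were among these calls. gfi1aa, morc3b and FP236812.8 lost their calls without either wild-type library, and etv2 lost its call without wild-type replicate 1. FP236812.8, tied in wild type, was not tested without either mutant library.

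Among the haemangioblast regulators, the transcription factors shared by early endothelial and blood precursors, 4 of 10 tested members fell, 0 rose and 6 did not pass. These 4 were tal1, lmo2, etv2 and gfi1aa. Adjusted over the list alone the count was 5, which added sox7 (55.0 ± 5.66 against 22.5 ± 2.12 normalised reads, log2 fold change -1.25 ± 0.44). The median log2 fold change of the list was -0.78, and 7 of its 10 members were lower in both mutant libraries than in both wild-type libraries. The median was -0.27 with no filter on low values and -1.35 over members with a mean value of at least 50. The list passed camera (adjusted p = 1.30e-20), but not with an estimated correlation (adjusted p = 0.301 with an estimated correlation) nor with fry's test for one direction (adjusted p = 0.0624). fli1a, an ETS factor of endothelial cells chosen after its values were seen, had a log2 fold change of -0.15 ± 0.26.

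Of the primitive erythroid genes, 3 of 19 tested members fell and 16 did not pass, and adjusted over the list alone the count was also 3. The 3 were tal1, lmo2 and gfi1aa, all shared with the haemangioblast list. The median was -0.22 and the list passed camera (adjusted p = 1.86e-05), but not with an estimated correlation (adjusted p = 0.320 with an estimated correlation). The correlation estimated for this list was -0.032, below the preset 0.01, so correlated members did not cause that loss. The median was -0.01 in mutant replicate 1 and -0.33 in mutant replicate 2, and -0.02 without mutant replicate 2. Without the members shared with the haemangioblast list, 16 genes were left, with a median of -0.12, and this remainder, chosen after seeing the data, did not pass camera when put in the list's place among the 18 (adjusted p = 0.95). nfe2, a factor of maturing red blood cells whose gene overlaps lima1a, had a log2 fold change of 0.72 ± 0.41 with an adjusted p of 1. Of the 19 genes, 6 were lower in both mutant libraries than in both wild-type libraries, tal1, lmo2 and gfi1aa among them. nfe2 was the 1 gene higher in both. gata1a, chosen after its values were seen, had low values, 14 and 20 in wild type and 3 and 11 in mutants. Its log2 fold change was -1.36 ± 1.08.

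None of the 22 tested endothelial genes passed the test, over all genes or adjusted over the list alone (0 in both), while 1 was higher and 3 were lower at an unadjusted p under 0.05. These 4 were flt1, a VEGF receptor, higher, and sox7, egfl7, a secreted endothelial factor, and dusp5, a MAP kinase phosphatase, lower. egfl7 stood at 43.0 ± 1.41 normalised reads in wild type and 15.5 ± 0.707 in mutants, a log2 fold change of -1.42 ± 0.54, and dusp5 at 46.5 ± 0.707 and 24.5 ± 6.36, a log2 fold change of -0.92 ± 0.46. flt1 was at 3 and 14 in the wild-type libraries and at 13 and 69 in mutant replicates 1 and 2. The list's median was -0.01 with a camera adjusted p of 0.605, and fry's test for change in either direction gave an adjusted p of 0.0324. Of the 22 genes, 6 were lower in both mutant libraries than in both wild-type libraries, and 1 was higher in both. The members had low values, with a median mean value of 32.6. Mutant replicate 2, with its raised low values, was the highest library in 7 of the 22, against 25% by chance. That count is too small to show whether raised low values affected this list.

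None of the 7 primitive myeloid and 16 cardiac mesoderm genes tested passed limma, over all genes or adjusted over the list alone (0 in both), and 0 and 1 of them had an unadjusted p under 0.05. limma-voom called 0 of the endothelial, myeloid and cardiac genes. The myeloid median was 0.11 (camera adjusted p = 0.635). cebpa, a factor of myeloid differentiation, stood at 252 ± 5.66 in wild type and 271.5 ± 16.3 in mutants, a log2 fold change of 0.11 ± 0.18, and the changes of cxcr4b, a chemokine receptor, and cybb, which overlaps dynlt3 and xk, were -0.26 ± 0.41 and 0.17 ± 0.42. csf1ra, the receptor of macrophage colony-stimulating factor, was at 7 and 2 in wild type and at 11 and 21 in mutants. The cardiac median was -0.06 (camera adjusted p = 0.577). The cardiac factors gata4, gata5 and mef2ca had log2 fold changes of -0.41 ± 0.22, -0.28 ± 0.17 and -0.32 ± 0.26. vmhc, the ventricular myosin heavy chain, was at 20 and 145 in wild-type replicates 1 and 2 and at 12 and 50 in mutants. It differed more within wild type than between the groups, and replicate 2 was higher in both. Its log2 fold change was -1.10 ± 0.50, and with tied genes left out, chosen after seeing the data, it passed as lower without wild-type replicate 1 (-2.50, adjusted p = 0.00416) but stood at 0.29 without wild-type replicate 2. Its neighbour vmhcl, chosen after its values were seen, also passed without wild-type replicate 1 (-2.34, adjusted p = 0.016).

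The axial mesoderm and hatching gland list also passed camera (median -0.18, adjusted p = 0.00104), but not with an estimated correlation (adjusted p = 0.819 with an estimated correlation), and 0 of its 20 tested members passed, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05, and 0 with limma-voom). The hatching gland enzymes ctslb and he1a, which overlap near-identical copies, had log2 fold changes of -0.78 ± 0.31 and -0.51 ± 0.24. Of the 20 tested members, 19 had a mean value of at least 50. Over all genes at that level, the median of mutant replicate 2 minus mutant replicate 1 was -0.13. The lower values of the list are therefore not shown to be particular to this tissue. The list's median was -0.12 in mutant replicate 1 and -0.25 in mutant replicate 2, and without mutant replicate 2 it no longer passed (median -0.12, adjusted p = 0.173).

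In the other 12 lists 0 members passed, over all genes or adjusted over the list alone, and no list passed camera. At an unadjusted p under 0.05 limma held 3 higher and 4 lower members. limma-voom called 1, the yolk apolipoprotein gene apobb.1, chosen after its values were seen, at -0.14. The median log2 fold change was 0.06 for pronephros, -0.01 for paraxial mesoderm and somite, -0.07 for differentiating muscle, -0.06 for neural tube and -0.02 for neural crest. It was 0.03 for endoderm, -0.10 for epidermis and enveloping layer, -0.13 for yolk syncytial layer and -0.02 for the p53 stress response. It was 0.01 for the bHLH-PAS partners and paralogues of npas4l, 0.03 for maternal transcripts and 0.04 for posterior Hox genes. The lowest camera adjusted p among these lists was 0.0712, for epidermis and enveloping layer, whose median was 0.08 in mutant replicate 1 and -0.23 in mutant replicate 2. The test recovered 50.7% of 2-fold changes in simulations simpler than these data, so changes of that size in single members may often have been missed.

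**Figure D3:**
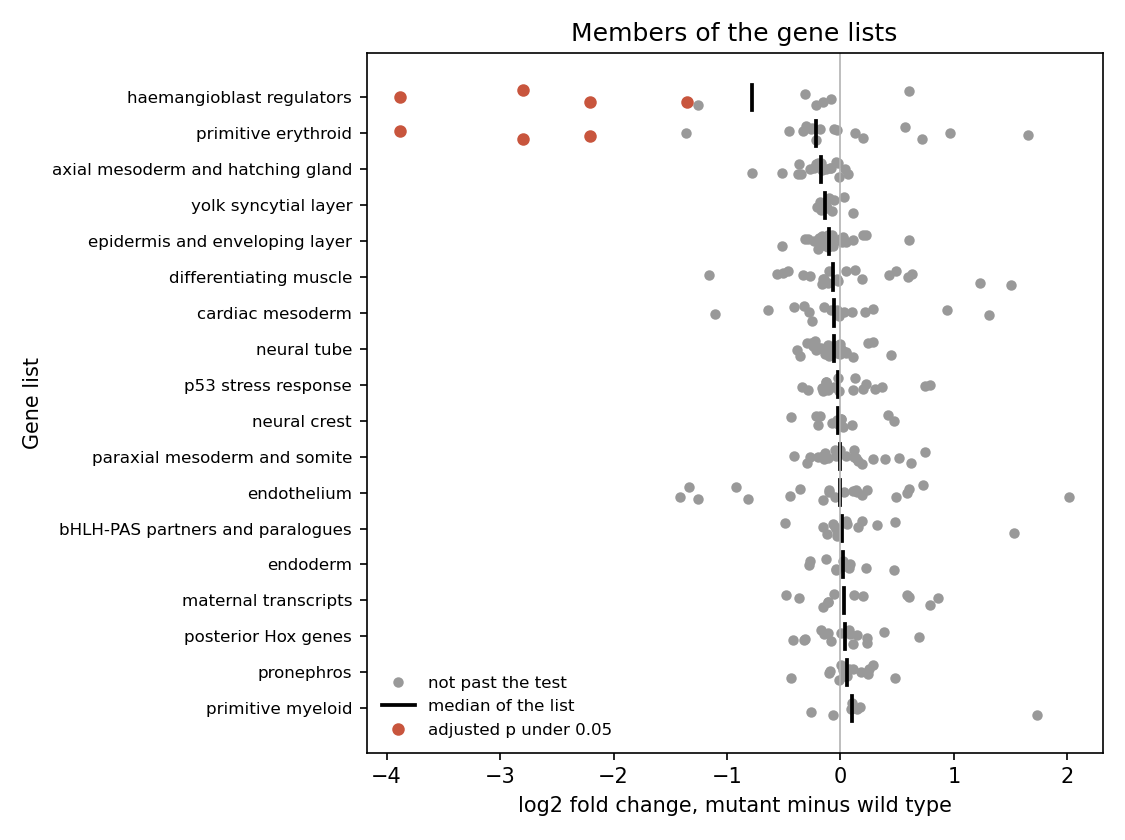
log2 fold change of mutants minus wild type (x axis) for each tested member of the 18 gene lists (y axis, ordered by median); red points have an adjusted p under 0.05, grey points do not, and black bars are the medians of the lists. The 4 red points of the haemangioblast list lie between -3.88 and -1.35, and the 3 of the erythroid list are the same genes as 3 of those 4.

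Of the gene families summed for each library, nuclear ribosomal RNA, added after seeing the data, took 1.48% and 1.24% in wild-type replicates 1 and 2 and 1.11% and 1.19% in mutant replicates 1 and 2. Histone genes took 1.29%, 1.26%, 1.17% and 1.18% in the same order, and cytosolic ribosomal protein genes 3.42%, 3.35%, 3.58% and 3.18%. The 2 haemoglobin genes of the table took at most 0.0002% of any library, and polymorphic immune genes, which differ between strains, took between 0.0053% and 0.008%.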

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

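All 8 called genes kept their direction in every alternative that tested them. Scaled to totals without mitochondrial, ribosomal RNA and haemoglobin genes, 15 genes passed, 2 higher and 13 lower, and 5 lists; the 8 were among the 15. 2 genes were higher with upper-quartile scaling, with a mean value of at least 50 and with quantile normalization. 6 lists passed with no filter and 5 with limma-voom, which kept 5 of the 8 genes. Leaving out each library in turn, the planned fits called 0 genes in each direction, because tied values gave variances of 0, and 1 to 4 lists. With tied genes left out, chosen after seeing the data, they called 6 to 219 genes, 2 to 23 higher and 4 to 196 lower, and 3 to 6 lists; fewer libraries were left, and the lone library of a group was assumed to vary like the other pair. Over all these fits the erythroid median ran from -0.33 to -0.023, the axial mesoderm and hatching gland median from -0.25 to -0.092, the p53 median from -0.27 to 0.15 and the epidermis median from -0.23 to 0.075. Without mutant replicate 2 the p53 list passed at its highest value, and with tied genes left out so did the epidermis list; the cause was not tested. With an estimated correlation, and with fry's test for one direction, 0 lists passed (fry's test for either direction passed endothelium, adjusted p 0.0324): the medians were -0.78 (haemangioblast; adjusted p 0.301 and 0.0624), -0.22 (erythroid; 0.320 and 0.234) and -0.18 (axial; 0.819 and 0.816). The replicate block called 9 genes, 8 shared, and changed no other call. Over all genes tested, deviations of libraries with the same number correlated at 0.009, which showed no pairing over the genes as a whole. A pairing limited to some genes, or hidden by the differences of mutant replicate 2, could not be seen this way. vmhc, tnnt2a (3 and 39 in wild type, 2 and 21 in mutants) and myh6 (2 and 25, 7 and 35) were higher in replicate 2 of both groups. These cardiac genes were chosen after their values were seen, and others, gata4 and bmp4 among them, were lower there. Whether libraries with the same number share a cause in such genes was not tested. The planned count tests were not run, because the values are not counts.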

Other observations

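The tests of the copies of H2B, the tests of the small RNAs, the test of depth and the test of how concentrated the excess is were chosen only after the result was seen; the tests of gene span, of the share of raised genes, of the neighbours of per1b and of the median absolute change of the clock genes were fixed before their values were examined. Most histone genes had lower values in mutants, without passing every test as a family. Of 136 tested histone genes, 84 were lower in both mutant libraries than in both wild-type libraries (61.8%, against 16.7% by chance), 7 were higher in both, and 2 passed limma as single genes. Among 10 gene groups, some overlapping, chosen after seeing the data, the histone genes passed camera (adjusted p = 1.44e-19) but not with an estimated correlation (adjusted p = 0.209 with an estimated correlation), and near-identical copies are not independent. Their median log2 fold change was -0.18, with medians of -0.12 in mutant replicate 1 and -0.23 in mutant replicate 2, and it stayed between -0.18 and -0.10 under the 4 other scalings. Outside the chromosome 7 cluster of the called H2B genes, 120 histone genes had a median of -0.18. The spliceosomal and nucleolar small RNAs, 36 snRNA and 121 snoRNA genes, had a median of -0.36 (-0.45 to -0.30 under the 4 other scalings). 65 of these 157 genes were lower in both mutant libraries and 2 were higher in both, while 0 passed limma as single genes (20 lower and 0 higher at an unadjusted p under 0.05, and 0 called with limma-voom). Among the alternatives, 1 of them was called lower with a mean value of at least 50, and with tied genes left out 2 were without mutant replicate 1 and 4 without mutant replicate 2. As a group they passed camera (adjusted p = 6.99e-13) but not with an estimated correlation (adjusted p = 0.209 with an estimated correlation). Their medians were -0.40 in mutant replicate 1 and -0.28 in mutant replicate 2, and the median difference between the wild-type replicates was 0.18.

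A move of reads among near-identical copies keeps their sum, so for the H2B genes as a whole it is argued against by the share of each library in all 34 H2B genes. It was 0.400% and 0.390% in wild type and 0.347% and 0.357% in mutants, a mean difference of -0.0434 where libraries of a group differed by at most 0.0104. For the 2 called H2B genes alone it stays open: their summed value changed by -434.5, while that of the other 32 differed by up to 2278 within a group. A lower recovery of short or non-polyadenylated RNA in the mutant libraries is a candidate explanation for the lower histone genes, but the values do not decide it. The snRNA and snoRNA genes were lower as well, with a median of -0.36. The 54 genes of the biotype misc RNA had a median of -0.16, but of -0.0016 in mutant replicate 1 and -0.33 in mutant replicate 2, and limma-voom called 2 of them, both lower. These classes differed in which mutant library was lower. The median of mutant replicate 2 minus mutant replicate 1 was 0.44 over snRNA, 0.041 over snoRNA (95% bootstrap interval -0.16 to 0.18) and -0.29 over misc RNA. It was -0.13 over histone genes and also -0.13 over all genes with a mean value of at least 50. Nuclear ribosomal RNA took a lower share in both mutant libraries (1.11% and 1.19%) than in wild type (1.48% and 1.24%), where the replicates differed as well. A difference in histone transcription or cell division in mutants was not tested and stays open.

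Mutant replicate 2 held raised values in genes that were near 0 in the other libraries. Deeper sequencing is argued against by its 7208000 reads in genes, the lowest of the 4 libraries. Among genes with a mean under 10 in the other libraries, the top 1% of the 7000 raised genes carried 5.75% of the excess and no gene exceeded 97. This argues against RNA of a cell type absent from the other libraries, which would put the excess into that type's abundant transcripts. It cannot decide on a cell type that the other libraries hold as well, because its abundant transcripts lie outside these genes. The share of genes in which this library was highest, 53.7% of 4111 against 25% by chance, decided nothing. Reads spread over gene bodies, from genomic DNA or unprocessed RNA, may account for the excess, which rose with gene span (Spearman's rho 0.38 across genes, which are not independent; median excess -1 in genes under 1 kb and 10.5 over 50 kb). No other biological explanation was tested.

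per1b was higher in both mutant libraries. A regional effect is argued against by its 29 tested neighbours within 1 Mb, whose median log2 fold change was 0.029 (95% bootstrap interval 0.004 to 0.12). A difference in light or time of day at collection, as the cause of the change in per1b, stays open. The 25 other clock and light-induced genes with a mean value of at least 50 had a median absolute log2 fold change of 0.10. Its 95% bootstrap interval, 0.06 to 0.16, lay under the bound of 0.3 fixed beforehand. That median leaves out genes with lower values and ignores direction, so it cannot decide the question. Of the 33 clock and light-induced genes tested besides per1b, 9 were higher in both mutant libraries (27.3%, against 16.7% by chance) and 1 was lower in both. Their median log2 fold change was 0.06 (95% bootstrap interval -0.01 to 0.24), and as a group they passed camera toward higher values (adjusted p = 0.00895), but not with an estimated correlation (adjusted p = 0.209 with an estimated correlation). The 9 include cry1ab (20 and 19 against 48 and 41), per3 (339 and 378 against 435 and 533) and ciarta (94 and 143 against 191 and 157), chosen after their values were seen, and 0 of the 33 passed limma (3 at an unadjusted p under 0.05; per3 alone passed without mutant replicate 1 with tied genes left out). The labels give no collection time, and a difference of strain background was not tested.

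Of the 143 genes with an unadjusted p under 0.01 by limma, where chance would give 167, 4 lay on chromosome 13 of the table (2.80%, against 3.80% of the genes tested). The split of the 4 libraries by genotype called 8 genes, the split by replicate number 1 and the remaining split 0; 3 splits are too few for a share under 0.05.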
